A study of Saccharomyces cerevisiae with 46 samples.

How the data were processed

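Replication was followed in budding yeast by comparative genome sequencing, in which genomic DNA from cells copying their chromosomes is sequenced beside DNA from unreplicated G1 cells of the same strain, so that copied regions carry more reads. The 46 libraries came from 10 strains of the W303 background, each arrested in G1 with the mating pheromone α-factor (5 µg/ml) and released into hydroxyurea (HU), a drug that limits deoxyribonucleotides and slows replication forks. Each strain had 1 G1 library and 1 library for each time after release: 30, 60, 90 and 120 min in 10 mM HU for 4 rad53 strains, 30, 60 and 90 min in 25 mM HU for 4 rad53 pol2D strains with POL2 on a plasmid, which are named by their plasmid and EXO1 alone (pPOL2, ppol2-S430D, pPOL2 exo1D and ppol2-S430D exo1D), and 30, 60, 90 and 120 min in 50 mM HU for wild type and pol2-S430A. Strain, dose and time were taken from the sample titles.

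Per the labels, reads were mapped to the reference genome and S/G1 read ratios were the authors' measure of replication. The submitters' processing notes name Bowtie2 2.3.5.1, SAMtools 1.9 and bedtools 2.29.0 without stating roles or parameters, and the genome build is not given in the sources used here. Chromosome names and ends in the deposited tables matched those of the R64 assembly, the assembly of the gene table used for names and gene positions. Origin positions and strain-specific spans are given in the coordinates of the deposited tables, counted from 1. The deposited values were whole-number read counts in consecutive 100 bp bins, 121579 bins per library, not normalised and not pooled. Between 6.14% and 6.41% of bins were empty in a library, mostly in repeated sequence. Whether repeated sequences lost reads through a mapping filter is not given in the sources used here, so copy numbers of repeats are not comparable with those of unique sequence.

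Everything from here on was computed from these counts with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Of 120721 nuclear bins, 111274 (92.2%) were kept, those with a G1 count between 0.25 and 4 times the library's median in every G1 library. Each HU library was divided by the G1 library of its own strain over the kept bins, scaled by library totals. The level taken as unreplicated was the 5th percentile of 10 kb running means of this ratio. The copy-number excess is the ratio over that level minus 1, in percent, so that 0% stands for unreplicated and 100% for copied in all cells. The scale is relative. If the least copied 5% of windows were partly copied, all excesses of that library are too low.

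No annotated origins were used here. Origins were maxima of the excess in the pooled HU libraries, smoothed over 2 kb, with a prominence of at least 10 percentage points and at least 5 kb apart. An origin's excess was measured over 1 kb on either side. Origins with an excess of at least 25% in the 8 pooled wild type and pol2-S430A HU libraries are called active and those under 10% inactive. All 36 HU libraries, most of them of rad53 strains, were pooled to find the origins, so inactive origins entered mainly as peaks of the rad53 libraries. An active origin is called isolated when no other origin with an excess of at least 25% in any 60 min HU library lay within 15 kb. The tract half-width is the distance from the origin at which the mean profile of isolated active origins falls to 0.5 of its centre value, searched up to 30 kb. Being relative to the centre, it also becomes smaller when the centre alone is higher. Neighbours farther than 15 kb remain, so in late libraries the half-width includes copying from neighbouring origins as well as the tract itself. The genome mean is the mean excess over kept 1 kb bins. The same measures in each G1 library over the pooled other G1 libraries gave the background. A further measure, the excess at 10 kb in percent of the excess at the centre, was added after seeing the data, because the half-width of wild type at 120 min lay beyond 30 kb.

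The 7 comparisons set each mutant against its parent at the same dose and time: rad53 pol2exo-, rad53 exo1D and rad53 pol2exo- exo1D against rad53, the plasmid strains ppol2-S430D, pPOL2 exo1D and ppol2-S430D exo1D against pPOL2, and pol2-S430A against wild type. The 90 min library, the latest time shared by the 3 doses, gives the main value. With 1 library per strain, dose and time there are no replicates, so no test between strains was made at a given time. Added after seeing the data, mutant and parent were paired by time, and the mean difference was given an exact two-sided sign-flip permutation test. Differences are medians over origins of the paired difference, mutant minus parent, with a 95% bootstrap interval over origins (1000 resamples), or over 50 kb blocks for the genome mean. Differences at single origins carry a 95% interval from Poisson counting. These intervals describe these libraries, cover counting error and the spread over origins only, and leave out differences between cultures. Reads without molecular identifiers are not independent molecules, so counting intervals are lower limits of the error. A count of 0 was given an upper limit of 3 counts.

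Libraries held 2520088 to 4433179 counts, with a median of 20 to 36 counts per kept bin. The 10 mM set spanned this range, the 25 mM set ran from 3964970 to 4363845 and the 50 mM set from 2987664 to 3347039. In G1 against pooled G1 ratios, 8.74% of 2860 origin values lay outside their 95% counting interval, and their standardised values had an SD of 1.25, so that counting covered most but not all of the technical spread. Of the pairs of libraries compared bin by bin, the closest, the G1 libraries of the pPOL2 and pPOL2 exo1D strains, had a chi-square of 1.03 per bin. They were told apart by EXO1, so no library was counted as deposited in 2 copies.

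The procedure was tested on simulated counts drawn at the depth of the real libraries, with 286 origins of which 100 were changed by 20 points. For pol2-S430A against wild type, 38% and 45% of changed origins were called from the counting interval in 2 simulations, against 4.30% and 2.69% of unchanged ones, so that most changes of this size are missed at single origins. Planted half-widths of 5, 7, 10 and 14 kb came back as 5.57, 7.62, 10.9 and 16.1 kb. A planted difference in the genome mean of 6.09 points came back as 5.94, but a planted difference of -2.39 between wide tracts came back as -0.697. For rad53 exo1D against rad53, 30% and 43% of changed and 2.15% and 5.38% of unchanged origins were called, and planted genome differences of 7.52 and -3.87 points came back as 6.09 and -0.965. With half-widths planted at 14 kb in the parent and 10 kb in the mutant, differences at origins came back too high, by a median of 4.59 points at changed and 4.49 at unchanged origins for rad53 exo1D against rad53, and by 3.38 points at changed origins for pol2-S430A against wild type, where the error at unchanged ones was -0.114. With 5 kb and 7 kb the median errors lay between -1.63 and 0.0994 points.

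Comparisons, measures, classes, lists and the naming rule were fixed before the data were examined. The rule names, in each comparison, the 5 origins with the largest increase and the 5 with the largest decrease at 90 min whose 95% counting interval excludes 0 and whose difference keeps its sign at every matched time from 60 min on. It also names EXO1, POL2, RAD53, SML1 and up to 10 genes, the longest first, that fell under 10% of the median gene in any G1 library. Gene and origin lists were tRNA genes, ribosomal protein genes, histone genes, ribonucleotide reductase genes and origins within 30 kb of a chromosome end. A list's median was placed among those of 10000 random lists of the same size, matched on distance to the nearest origin for genes and drawn from all origins for origins. Lists of origins by ARS name, origins near centromeres, LTR and Ty elements and the 2-micron plasmid were not analysed here, and a correction for GC content was not run, since no genome sequence or such annotation was used here.

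Alternatives were the pooled G1 libraries of a dose set as the denominator, the 20th percentile as the unreplicated level, no unreplicated level, a window of 2.5 kb, no bin filter, a stricter prominence of origins, an activity threshold of 40%, isolation at 10 and 20 kb, and the 99th percentile of the background. Added after seeing the data were libraries thinned to 2295374 kept counts, the measures without chromosomes I and XII, isolation at 30 and 40 kb, and a scale on which the 5% most copied windows hold 2 copies.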

Results

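The data cover 36 HU libraries and 10 G1 libraries of 10 yeast strains, with 1 library per strain, dose and time and 2520088 to 4433179 counts each. The series title names the question: whether the checkpoint holds back the exonuclease of DNA polymerase ε, and what this means for forks attacked by resection. RAD53 encodes the checkpoint kinase that restrains late origins and protects forks when nucleotides run short. POL2 encodes the catalytic subunit of polymerase ε, which carries a 3'-5' proofreading exonuclease, and EXO1 encodes a 5'-3' exonuclease that resects DNA ends. The pol2exo- allele is named for the loss of the POL2 exonuclease. In pol2-S430A and ppol2-S430D the serine at position 430 of the protein is replaced by alanine, which cannot be phosphorylated, or by aspartate, often used in place of a phosphorylated serine.

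Coverage of the engineered genes followed the labels. In the G1 libraries of the 4 exo1D strains, EXO1 held 2 counts in rad53 exo1D, which is 0.304% of the median gene with an upper 95% bound of 1.099%, 0 counts in rad53 pol2exo- exo1D, which allows up to 0.449% by the limit of 3 counts and 0.553% by the interval used for the other strains, 3 counts in pPOL2 exo1D, with an upper bound of 1.26%, and 6 counts in ppol2-S430D exo1D, with an upper bound of 1.962%. In the other 6 strains EXO1 lay between 0.933 and 1.03 times the median gene. The nearly empty span ran from 392501 to 394500 on chromosome XV, or to 394400 in ppol2-S430D exo1D. POL2 stood at 1.48 times the median gene in G1 in pPOL2, 1.497 in pPOL2 exo1D, 2.01 in ppol2-S430D and 2.12 in ppol2-S430D exo1D, so the plasmid strains carried more than 1 copy per genome, and the S430D plasmids more than the POL2 plasmids. In HU, POL2 reached 2.06 to 3.11 in these strains. The chromosomal deletion cannot be read from these bins, because the plasmid copy maps to the same place. LEU2, a leucine synthesis gene widely used as a marker, stood at 2.56 to 3.24 in the same 4 strains in G1. TRP1, a tryptophan synthesis gene also used as a marker, stood at 2.10 and 1.82 in the 2 plasmid strains without EXO1. RAD53 lay between 0.927 and 1.046 and SML1, which encodes an inhibitor of ribonucleotide reductase, between 0.806 and 1.099 in all 10 G1 libraries. Point mutations cannot be seen in bin counts. Of 6036 genes, 310 fell under 10% of the median gene in at least 1 G1 library and 286 of these in all 10. The longest were the ribosomal RNA genes RDN37-1 and RDN37-2, the subtelomeric helicase genes YRF1-6, YRF1-7, YRF1-3 and YRF1-8, the subtelomeric YIL177C and YJL225C, and the retrotransposon genes YPL060C-A and YHL009W-B, all repeated sequences.

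Whole chromosomes were at equal levels in G1 with 2 exceptions. In rad53 exo1D, chromosome I stood at 1.997 times the median chromosome, against 0.985 to 1.01 in the other 9 strains. In rad53 pol2exo- exo1D, chromosome XII stood at 1.11, against 0.973 to 1.02. The other 158 of 160 values lay between 0.973 and 1.02. Dividing by the strain's own G1 library removes such a gain from the excess. Dividing by the pooled G1 libraries of the dose set does not remove it in full. The 2 pol2exo- strains carried a stretch at the left end of chromosome VII, from 801 to 6300, at 1.03 and 0.908 times the median bin, which held at most 3 counts in the other 8 strains. Both strains with raised chromosomes enter the 10 mM comparisons, and their half-width and active-origin differences kept their direction without chromosomes I and XII.

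**Figure D1:**
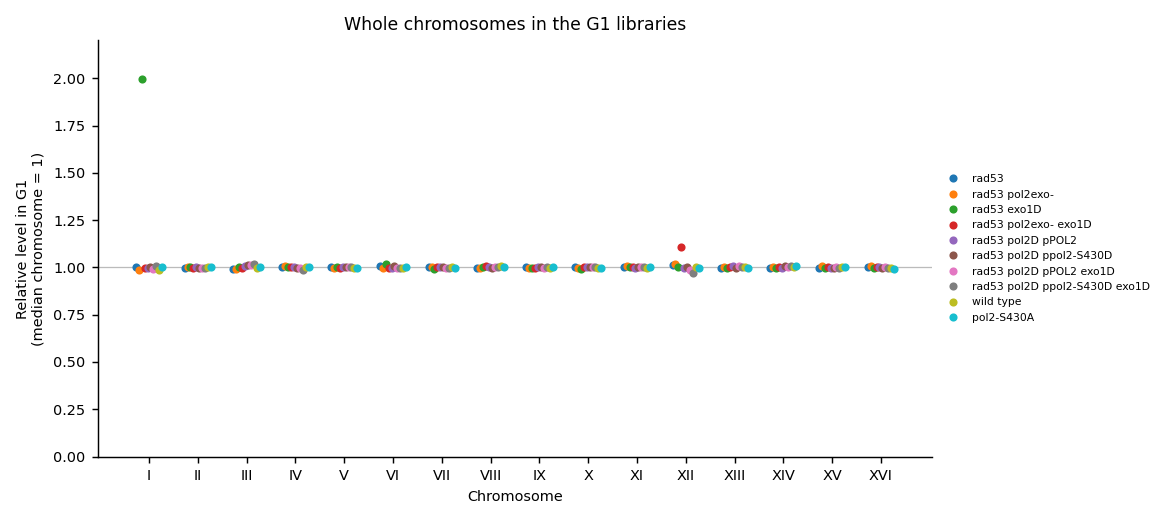
Level of each of the 16 nuclear chromosomes (x axis) in the 10 G1 libraries relative to the median chromosome of the library (y axis, 1 is equal), 1 point per strain and chromosome. Chromosome I in rad53 exo1D lies at 1.997 and chromosome XII in rad53 pol2exo- exo1D at 1.11, while the other 158 points lie between 0.973 and 1.02.

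The pooled HU profile held 286 origins with a median spacing of 36.65 kb. Of these, 142 were active, 67 inactive and 77 in between in wild type and pol2-S430A. By the gene table, 155 lay within a gene, and 131 active origins were isolated. In G1 libraries measured the same way, the median excess at origins was 2.40% to 7.12% and the 95th percentile over all G1 values was 14.3%. An origin above 14.3% is counted as copied above background.

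Wild type cells in 50 mM HU copied from the active origins, while the inactive ones, a class set in these libraries and those of pol2-S430A, stayed near the G1 background for 90 min. The median excess at active origins was 32.2% at 30 min, 49.5% at 60 min, 77.8% at 90 min and 76.8% at 120 min, while that at inactive origins was 8.60%, 5.53%, 8.69% and 27.1%. At 60 min 184 of 286 origins, or 64.3% (95% exact binomial interval 58.5% to 69.9%), were above background, and 15 of the 67 inactive ones. In rad53 cells in 10 mM HU, 282 of 286 origins, or 98.6% (96.5% to 99.6%), were above background at 60 min, among them 65 of the 67 inactive ones, and the median excess at inactive origins was 43.6%. Part of this contrast is fixed by selection, because the pooled libraries that gave the origins included those of the rad53 strains, while the inactive class was set by a low excess in wild type and pol2-S430A. In rad53 pPOL2 cells in 25 mM HU, 65 of the 67 inactive origins were above background at 60 min, with a median excess of 34.0%, and the same limit applies. The 3 doses differ, so checkpoint and dose cannot be told apart in this contrast. In rad53 the excess at active origins was highest at 60 min, at 77.4%, and lower at 120 min, at 60.7%. In pPOL2 it was 50.9% at 60 min and 49.4% at 90 min.

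**Figure D2:**
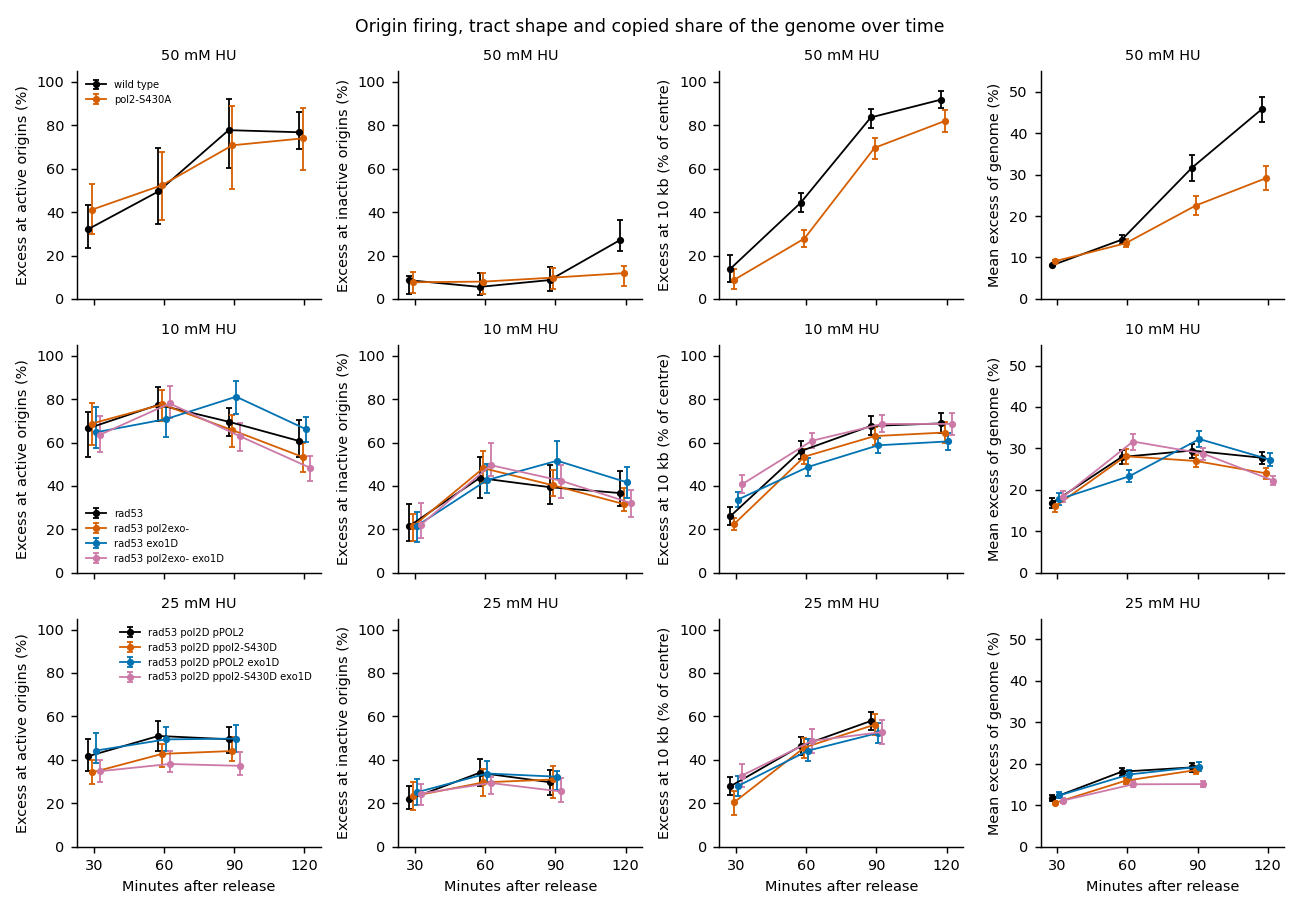
Time after release (x axis, minutes) against the median excess at active origins and at inactive origins in percent (bars are quartiles over origins), the excess at 10 kb in percent of the centre (bars are 95% bootstrap intervals over origins) and the mean excess of the genome in percent (bars are 95% block bootstrap intervals), 1 line per strain, with 50, 10 and 25 mM HU from top to bottom. Inactive origins of wild type lie at 5.53% at 60 min in 50 mM HU and those of rad53 at 43.6% in 10 mM HU, a contrast in part fixed by how the class was set.

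With alanine in place of serine 430 of Pol2, in cells with an intact checkpoint, copied tracts around active origins were narrower at 90 and 120 min. At 30 min the half-width was 3.77 kb in pol2-S430A and 3.28 kb in wild type, 0.492 kb wider (95% interval 0.207 to 0.748), and the genome mean was 9.13% against 8.07%, 1.05465 points higher (0.758 to 1.41). In G1 the genome mean was 4.74% in pol2-S430A and 4.51% in wild type, so much of these 30 min values is background. With the most copied windows at 2 copies, a scale chosen after seeing the data, the 30 min difference turned to -8.34 points. At 60 min the half-width was 7.54 kb against 8.83 kb, a difference of -1.29 kb (-2.10 to -0.722). Over origins with no neighbour within 30 and 40 kb the 60 min intervals included 0 (-1.48 kb, -2.42 to 0.292, and -1.17 kb, -2.80 to 0.764). At 90 min in 50 mM HU the mean profile of 131 isolated active origins fell to 0.5 of its centre at 27.8 kb in wild type and at 13.7 kb in pol2-S430A, a difference of -14.1 kb (95% interval -17.1 to -11.4). In 22.9% of resamples the half-width lay beyond 30 kb and was set to 30 kb, so the lower bound is limited by the search. Because origins lay a median of 36.65 kb apart, half-widths of this size include copying from neighbouring origins. Over the 63 active origins with no neighbour within 30 kb the half-widths at 90 min were 22.1 kb and 11.9 kb (difference -10.3 kb, -12.5 to -6.64), and over the 29 with none within 40 kb 21.03 kb and 12.2 kb (-8.78 kb, -9.48 to -5.57). Both settings were chosen after seeing the data. At 120 min the half-width was 21.1 kb in pol2-S430A and was not reached within 30 kb in wild type. The excess at 10 kb was 83.6% of the centre in wild type and 69.6% in pol2-S430A at 90 min, a difference of -14.0 points (-19.3 to -9.00), and the difference was already -16.5 points (-21.8 to -11.6) at 60 min. With no neighbour within 30 kb these differences were -14.3 points (-23.1 to -6.33) at 90 min and -17.8 points (-26.7 to -9.90) at 60 min. With none within 40 kb they were -8.25 points (-19.5 to 1.64) at 90 min and -13.3 points (-26.7 to 0.0776) at 60 min. Only the 40 kb intervals included 0. The genome mean was 31.7% in wild type and 22.5% in pol2-S430A at 90 min, a difference of -9.13 points (-10.3 to -7.91), and 45.9% against 29.1% at 120 min.

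Active origins had more excess in pol2-S430A than in wild type at 30 min and, with the unreplicated level set as above, less at 90 min. At 30 min the median excess at active origins was 41.1% in pol2-S430A and 32.2% in wild type, a paired difference of 8.09 points (3.80 to 10.7), with 101 of 142 origins higher. At 60 min the difference was 0.793 points (-2.38 to 4.08), and at 90 min it was -6.71 points (-10.4 to -2.92), with 51 of 142 origins higher. With no unreplicated level the 90 min difference turned to 5.17 points, so its direction rests on that setting. Inactive origins differed by 1.02 points at 90 min (-2.29 to 6.76). At 120 min they had reached 27.1% in wild type and 11.9% in pol2-S430A, a difference of -17.1 points (-22.8 to -13.4), and 61 of the 67 were above background in wild type against 23 in pol2-S430A.

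Single origins beyond the counting interval were mostly lower in pol2-S430A. At 90 min 13 origins were higher and 32 lower in pol2-S430A beyond the counting interval, against 14.3 of 286 expected by counting alone and 23 between the 2 G1 libraries. Here and in the comparisons below, these 2 reference numbers are not split by direction. The 45 origins in both directions together exceeded both of them, and so did the 32 decreases alone. For the 13 increases no reference of 1 direction was computed, so those named here are not shown to be set apart from background. The origin at 302101 on chromosome XI, next to STB6, had 79.3% in wild type and 121% in pol2-S430A (difference 41.5, 95% counting interval 8.50 to 74.6). That at 843201 on chromosome XVI, between TDA6 and CUR1, went from 56.6% to 97.55%, and that at 1166701 on chromosome IV, between the glucose transporter gene HXT3 and SVF1, from 69.9% to 98.6%. The inactive origins at 1022601 on chromosome XII, in ECM7 near the silencing gene SIR3, and at 757801 on chromosome II, in PPS1 near RIF1, which encodes a protein that delays late origins, were 31.4 and 26.0 points higher. The largest decreases were at 90701 on chromosome XVI in IQG1, from 63.2% to 20.7% (difference -42.5, -66.8 to -18.3), at 167801 on chromosome III in RHB1 (-37.5), at 198201 on chromosome III in BUD5 beside the mating type locus (from 35.7% to 1.28%), at 553801 on chromosome XIII in FDO1 (-33.0) and at 207201 on chromosome X in MDV1 (-31.5). With no unreplicated level the half-width difference was -5.81 kb, still below 0. On the scale with the most copied windows at 2 copies, chosen after seeing the data, the genome mean difference was -1.48 points.

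**Figure D3:**
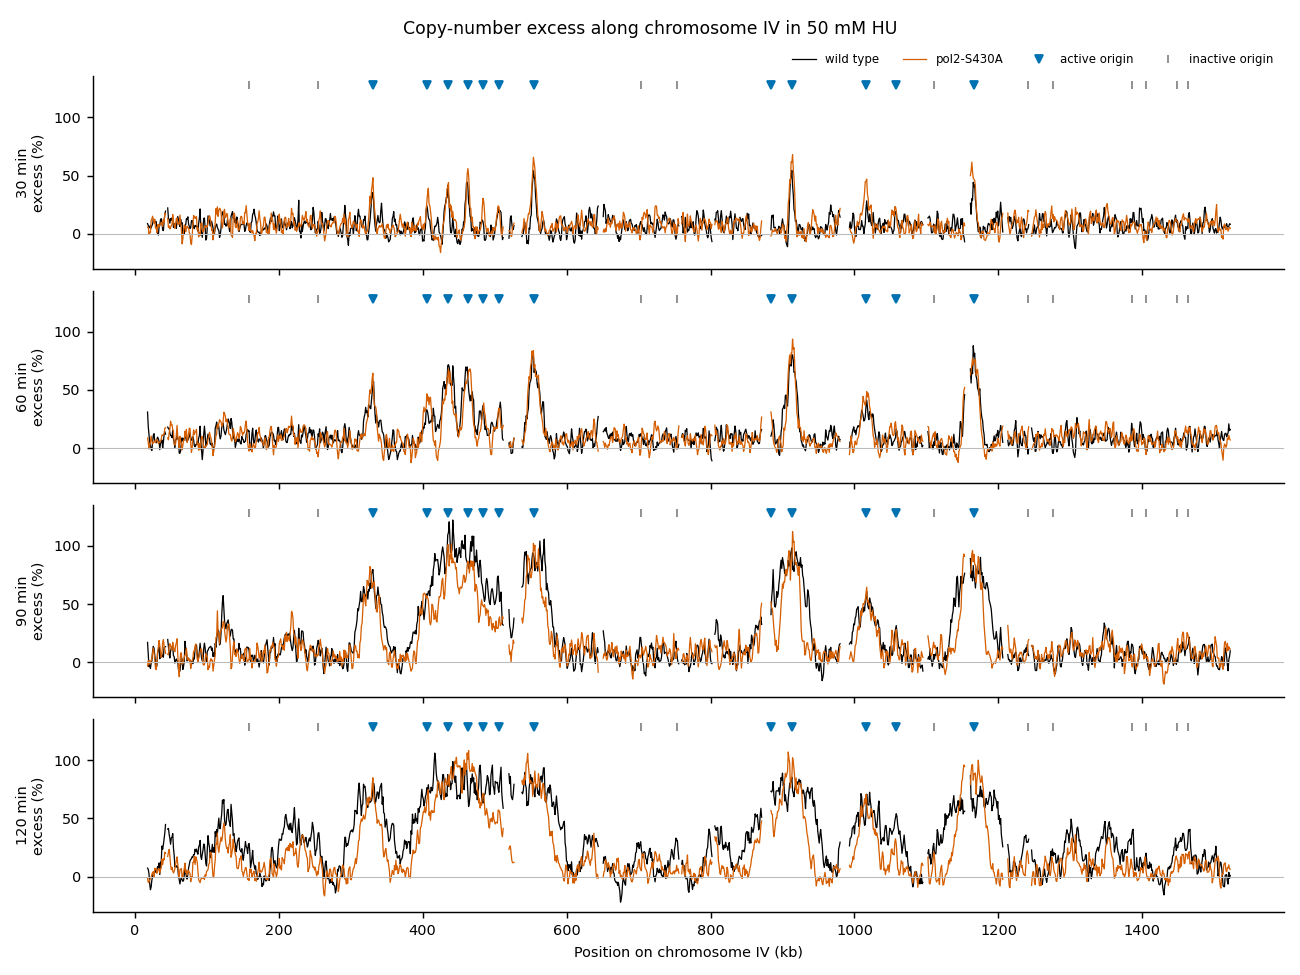
Copy-number excess (y axis, percent, means over 3 kb) along chromosome IV (x axis, kb) in wild type (black) and pol2-S430A (orange) at 30, 60, 90 and 120 min in 50 mM HU, with active and inactive origins marked at the top and gaps where bins were left out. Peaks start at the same origins in both strains and are broader in wild type from 90 min, where the half-width over all isolated active origins was 27.8 kb against 13.7 kb.

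In rad53 cells in 10 mM HU, strains with the exonuclease-deficient pol2exo- allele had less excess at active origins late in the time course. The paired difference from rad53 was 3.80 points (1.09 to 6.20) at 30 min, -0.0890 (-3.42 to 2.23) at 60 min, -3.46 (-6.71 to -0.173) at 90 min and -8.80 (-11.6 to -5.48) at 120 min. At 90 min 58 of 142 active origins were higher, and medians were 69.6% in rad53 and 65.7% in rad53 pol2exo-. The half-width was 14.8 kb in rad53 and 13.6 kb in rad53 pol2exo- at 90 min, a difference whose interval included 0 (-3.31 to 1.28). Inactive origins were 7.06 points higher in rad53 pol2exo- at 60 min (3.73 to 9.57) and differed by -4.69 points at 120 min (-6.52 to -2.43), 31.7% against 36.7% in rad53.

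At single origins, 8 were higher and 17 lower in rad53 pol2exo- at 90 min, against 14.3 expected by counting and 17 between the G1 libraries. The largest decreases were at 417901 on chromosome XI in ARC19, a subunit gene of the Arp2/3 actin complex, from 97.6% to 54.5% (-43.2, -71.9 to -14.5), at 161101 on chromosome X in MRS3, a mitochondrial iron carrier gene (-37.3), at 175901 on chromosome IX in XBP1 (-34.9), at 603401 on chromosome XII between ECM22 and CDC42 (-34.6) and at 43101 on chromosome XVI near the amino acid permease gene DIP5 (-34.3). The largest increases were at 633001 on chromosome XVI in NTO1, from 65.5% to 103% (37.4, 9.90 to 64.8), at 435001 on chromosome IV (34.8), at 417601 on chromosome X in NOP9 (28.1), at 553801 on chromosome XIII in FDO1 (27.9) and at 1006901 on chromosome XII in TSR2 (24.0). The genome mean was 2.51 points lower (27.0% against 29.5%), but its direction turned to 1.85 on the scale with the most copied windows at 2 copies. At 90 min the sign changed in 6 of the 7 comparisons, 1 of them with an interval that already included 0. Genome means are therefore given here with this limit.

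Without EXO1, rad53 cells had more excess at active origins and a smaller half-width at 90 min. The median was 81.1% in rad53 exo1D and 69.6% in rad53, a paired difference of 12.4 points (10.1 to 14.6) with 117 of 142 origins higher, and it was -8.69 points (-11.2 to -6.03) at 60 min and 4.89 (2.88 to 6.86) at 120 min. Inactive origins were 9.88 points higher at 90 min (6.61 to 13.2), 51.6% against 39.4%. The half-width was 11.7 kb against 14.8 kb at 90 min, a difference of -3.10 kb (-3.73 to -0.599), and 12.2 kb against 15.2 kb at 120 min. At 30 min it was wider, 7.68 kb against 6.61 kb. The half-width is relative to the centre, which was 81.2% in rad53 exo1D and 68.9% in rad53 at 90 min. At 5, 10, 15 and 20 kb the excess was then 64.1%, 47.7%, 32.8% and 28.9%. In rad53 it was 59.3%, 46.6%, 34.2% and 26.4%. Less copying away from origins is thus not shown at 90 min. At 90 min 34 origins were higher beyond the counting interval and 0 lower, against 14.3 expected and 16 between the G1 libraries. The 5 largest increases were at 89101 on chromosome XIV between the cyclin gene PCL1 and SNR40, from 43.2% to 94.5% (51.3, 26.2 to 76.4), at 213101 on chromosome XI between SRP21 and DGR2 (49.4), at 59401 on chromosome V between VMA8, a vacuolar proton pump subunit gene, and RML2 (48.4), at 753801 on chromosome IV in KGD2, an enzyme gene of the citric acid cycle (45.3), and at 981201 on chromosome XV near the translesion polymerase gene REV1 (39.4). The rise at active origins at 90 min was 6.45 points with no unreplicated level. In a simulation of this pair with tracts narrower in the mutant, unchanged origins came back 4.49 points too high. Thus part of the 90 min rise and much of the 120 min rise can come from the measure. The planted drop in half-width, from 14 to 10 kb, was larger than the observed drop, so the share is not known. The genome mean was 2.77 points higher at 90 min but differed by -4.66 points (-5.11 to -4.13) at 60 min and -0.425 points (-0.813 to -0.00542) at 120 min. On the scale with the most copied windows at 2 copies the differences were 1.78 points at 60 min, -4.88 at 90 min and -4.52 at 120 min.

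The strain rad53 pol2exo- exo1D, called the triple mutant, had the lowest excess at active origins and the largest half-width of the 10 mM set at 120 min. Active origins stood at 62.9% at 90 min, -6.53 points (-8.08 to -4.27) from rad53 with 41 of 142 higher, and at 48.4% at 120 min, -12.6 points (-14.3 to -10.3) with 23 of 142 higher. Its half-width was 15.5 kb at 90 min, 0.676 kb wider than in rad53 (0.0676 to 3.54), and 19.3 kb at 120 min, where the interval of the difference included 0 (-0.415 to 4.85). The excess at 10 kb relative to the centre did not differ from rad53 at these times, by 0.906 points (-4.46 to 5.98) at 90 min and -0.253 points (-6.91 to 6.47) at 120 min. The half-width was larger than in rad53 already at 30 min, 8.48 kb against 6.61 kb, a difference of 1.87 kb (1.30 to 2.60). Against rad53 exo1D, the strain with the same EXO1 deletion, active origins differed by -17.3 points at 90 min (-20.0 to -15.0), with 9 of 142 higher, and the half-width was 3.78 kb larger (3.15 to 5.07). The excess at 5, 10, 15 and 20 kb was then 53.0%, 42.0%, 33.1% and 26.9%. In rad53 exo1D it was 64.1%, 47.7%, 32.8% and 28.9%. When tracts were simulated as narrower in the mutant, unchanged origins came back 4.49 points too high. A larger half-width of this size in the mutant was not simulated, and part of the lower values of the triple mutant can come from the measure. At 60 min active origins were 7.54 points higher than in rad53 exo1D (5.94 to 11.6), with 106 of 142 higher, and inactive origins 9.69 points higher (4.59 to 13.6). Against rad53 pol2exo-, active origins differed at 90 min by -2.10 points (-4.75 to 1.002) and the half-width by 1.92 kb (1.38 to 4.09).

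At 90 min 8 origins were higher and 17 lower in the triple mutant than in rad53 beyond the counting interval, against 14.3 expected and 17 between the G1 libraries. The origin in ARC19 again had the largest decrease, from 97.6% to 41.4% (-56.2, -84.3 to -28.2), followed by those at 285101 on chromosome VII in COQ8, a ubiquinone synthesis gene (-40.8), at 441401 on chromosome X in MRX12 (-40.4), at 603401 on chromosome XII (-37.8) and at 331601 on chromosome XVI in the histone deacetylase gene HOS3 (-33.9). The origin near REV1 was 33.3 points higher, and those at 30401 on chromosome I between FLO9 and GDH3 (29.0), at 553801 on chromosome XIII (28.9), at 250501 on chromosome XIV between MRX7 and MER1 (26.9) and at 68201 on chromosome VI in MIL1 (26.8) followed. With pooled G1 libraries the origin in HOS3 turned to 4.84 and that at 553801 to -4.13, so these 2 directions rest on the choice of the G1 library. The genome mean difference from rad53 was 3.73 points at 60 min, -0.746 at 90 min and -5.503 at 120 min. With the most copied windows at 2 copies it was 1.70 points at 60 min, 5.38 at 90 min and 7.415 at 120 min.

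**Figure D4:**
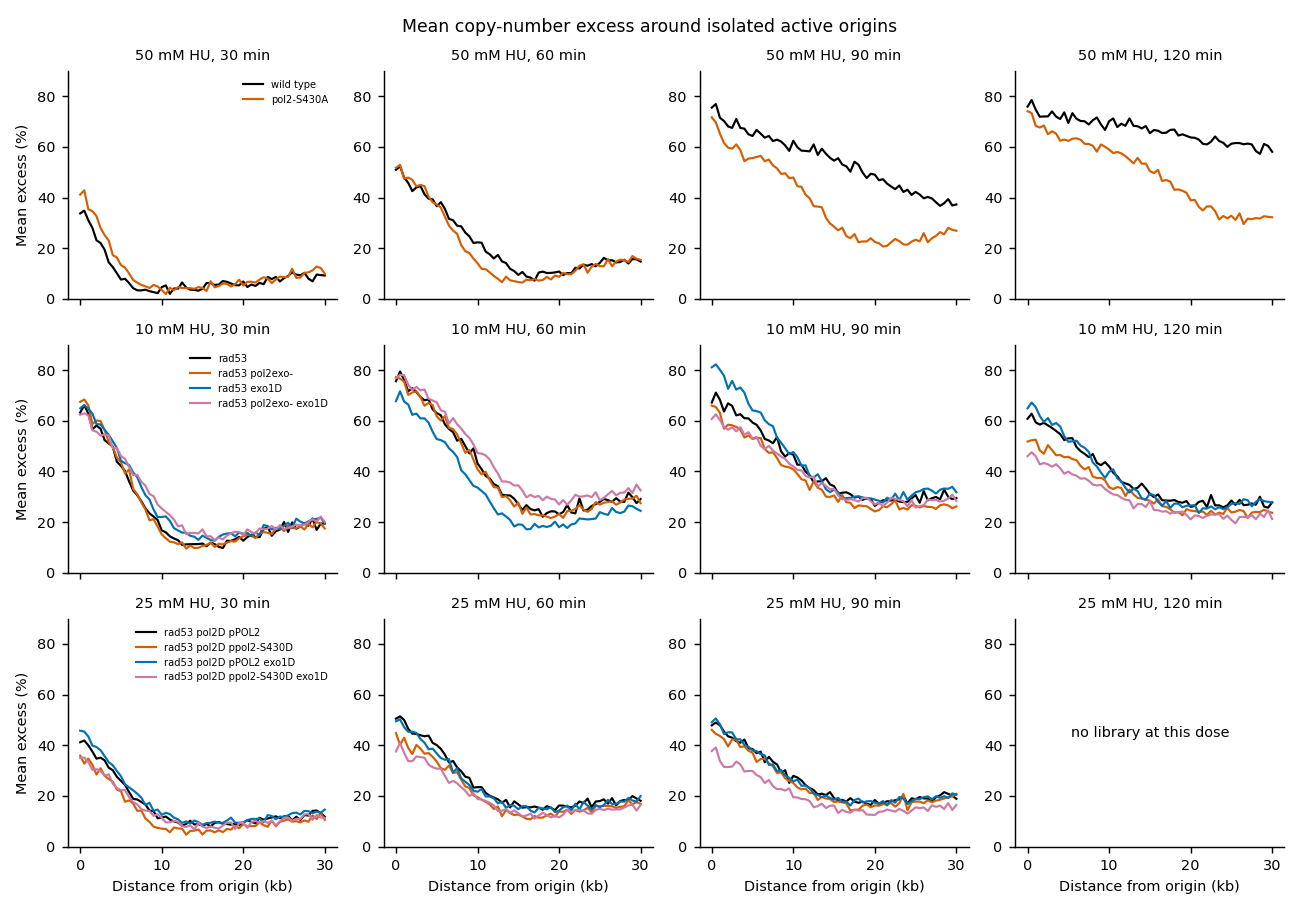
Mean copy-number excess (y axis, percent) against the distance from the origin (x axis, kb) over 131 isolated active origins, 1 line per strain, for 50, 10 and 25 mM HU from top to bottom and 30, 60, 90 and 120 min from left to right, with no library at 120 min in 25 mM HU. At 90 min in 10 mM HU rad53 exo1D has the highest peak and the smallest half-width. It is 11.7 kb, against 15.5 kb in rad53 pol2exo- exo1D, each relative to its own centre.

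In the plasmid strains in 25 mM HU, aspartate at position 430 of Pol2 went with less excess at active origins at every time and with little change in half-width. The median was 41.6%, 50.9% and 49.4% in pPOL2 at 30, 60 and 90 min and 34.1%, 42.7% and 44.0% in ppol2-S430D, with paired differences of -7.17 (-8.52 to -4.30), -8.93 (-10.7 to -6.45) and -5.81 points (-7.79 to -3.66). At 90 min 45 of 142 origins were higher. The half-width was 11.6 kb in both strains at 90 min, the interval of the difference ran from -1.51 to 2.32 kb, and the differences at 30 and 60 min were 0.212 and 0.0766 kb. The excess at 10 kb relative to the centre was lower in ppol2-S430D at 30 min, 20.4% against 27.8%, a difference of -7.37 points (-14.0 to -0.212), while the intervals at 60 and 90 min included 0. POL2 copies per genome also differed between these strains, 1.48 against 2.01 in G1. Single origins beyond the counting interval numbered 9 higher and 10 lower, against 14.3 expected and 10 between the G1 libraries. The largest decreases were at 356301 on chromosome IX in SGN1, near the DNA helicase gene MPH1, from 74.0% to 46.7% (-27.3, -51.1 to -3.48), at 252901 on chromosome II in FLR1 near the histone gene HHF1 (-26.8), at 486801 on chromosome II between TFC1 and PTC4 (-25.8), at 438201 on chromosome XV near ASE1 (-25.5) and at 499001 on chromosome XIV near FKH2, a transcription factor that sets the timing of early origins (-25.0). The largest increases were at 261701 on chromosome XIII in GLO1 (25.2), at 85201 on chromosome XV in TRM13 (23.3), at 175901 on chromosome IX in XBP1 (23.2), at 17201 on chromosome VII (22.6) and at 1063501 on chromosome VII near the biotin synthase gene BIO2 (21.9). With pooled G1 libraries the difference at active origins was -2.31 points at 90 min, and the genome mean difference of -0.663 points turned to 0.272.

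Without EXO1, the pPOL2 strain differed little from its parent. Active origins differed by 2.99 points (1.005 to 4.78) at 30 min, -1.35 (-3.10 to 1.55) at 60 min and 2.26 (0.154 to 5.19) at 90 min, with 83 of 142 higher at 90 min. The half-width was 10.9 kb against 11.6 kb (difference -0.695 kb, -1.90 to 1.57) and the genome mean differed by 0.171 points (-0.0939 to 0.435). At single origins 11 were higher and 5 lower, against 14.3 expected and 13 between the G1 libraries. The largest increases were at 64501 on chromosome VII in the phosphatase-associated gene SAP4, from 22.5% to 56.0% (33.5, 13.2 to 53.9), at 731401 on chromosome XII in HRI1 (30.5), at 1016401 on chromosome IV near MTH1 (28.4), at 642501 on chromosome XI between the silencing gene SIR1 and FLO10 (27.6) and at 42201 on chromosome I in PEX22 (27.6). The largest decreases were at 137601 on chromosome VI (-33.2), at 177101 on chromosome I near PAU7 (-28.7), at 356301 on chromosome IX in SGN1 (-26.8), at 230801 on chromosome XII near the thioredoxin gene TRX1 (-25.2) and at 438201 on chromosome XV near ASE1 (-24.7). The last of these was 0.882 when libraries were thinned to equal depth.

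With the S430D change and the loss of EXO1 together, the excess at active origins was the lowest of the 25 mM set at 60 and 90 min. The median was 34.7%, 38.0% and 37.2% at 30, 60 and 90 min, and paired differences from pPOL2 were -5.30 (-9.49 to -2.74), -11.2 (-14.3 to -8.29) and -11.2 points (-13.5 to -8.59), with 19 of 142 higher at 90 min. Against ppol2-S430D the difference was 1.40 points (-0.964 to 3.51) at 30 min, -2.60 (-4.66 to -0.202) at 60 min and -7.15 (-9.35 to -4.69) at 90 min, and against pPOL2 exo1D it was -11.7 points (-14.1 to -9.54) at 90 min. Inactive origins were at 25.4% against 29.6% in pPOL2 at 90 min, a difference of -2.63 points (-5.02 to -1.35). The half-width was 11.7 kb, with a difference interval of -1.89 to 2.27 kb. At 90 min 43 of 286 origins were lower beyond the counting interval and 0 higher, against 14.3 expected and 15 between the G1 libraries, and 32 of the 43 were active. The largest decreases were at 374201 on chromosome X near the nuclear pore gene NUP192, from 71.5% to 27.0% (-44.4, -66.8 to -22.1), at 177101 on chromosome I near PAU7 (-43.2), at 137601 on chromosome VI (-40.9), at 507401 on chromosome VII in ECT1, a phospholipid synthesis gene (-40.4), and at 356301 on chromosome IX in SGN1 (-38.6). The difference at active origins was -8.04 points with pooled G1 libraries and -5.40 with no unreplicated level, and the genome mean difference of -4.04 points turned to 7.82 with the most copied windows at 2 copies.

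Of the 5 gene and origin lists, 3 stood apart from random lists in most HU libraries. tRNA genes, of which 266 of 275 were measured at a median of 6.99 kb from an origin, were copied more than the central 95% of 10000 random lists matched on distance to the origin in 34 of 36 HU libraries and less in 0. At 90 min their median excess was 55.9% in wild type, against 26.8% for the random lists, 35.9% against 16.4% in pol2-S430A and 41.4% against 33.9% in rad53. Matching was to the nearest origin of any class, so a list that lies near active origins can stand above the random lists for that reason. The 8 histone genes were above in 30 of 36, with 88.4% against 34.5% in wild type and 94.7% against 21.2% in pol2-S430A at 90 min. The limit of class applies to them as well. Random genes were drawn separately, so histone genes that lie side by side are not allowed for. The same genes enter every library, so counts of libraries are not independent. The 12 origins within 30 kb of a chromosome end were below in 27 of 36 and above in 0, with 8.21% against 42.9% in wild type, 13.6% against 33.1% in pol2-S430A and 34.3% against 59.2% in rad53. Of these 12 origins 8 were inactive and 2 active, and the random lists were not matched on class. The low values in wild type and pol2-S430A therefore largely restate the class. Ribosomal protein genes (122 of 132 measured) were above in 2 and below in 2, and the 4 ribonucleotide reductase genes were above in 1 and below in 0. The 10 G1 libraries, each over the pooled other G1 libraries, gave the background of the lists. There tRNA genes were above in 1 and below in 3, and histone genes above in 1 and below in 1. Origins near ends were above in 3 and below in 0. Ribosomal protein genes were above in 3 and below in 2, and ribonucleotide reductase genes above in 1 and below in 0.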

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

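The tests of explanations in this part were all chosen after the results they measure had been seen.

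Chromosome I stood at 1.997 times the median chromosome in the G1 library of rad53 exo1D, a signal outside the origin measurements and above the 0.985 to 1.01 of the other 9 strains. Bias along the chromosome is argued against, since the lowest 10 kb window over the 5 libraries of this strain was at 1.86. A mixture with another library of the series is argued against, since the highest level in the other G1 libraries was 1.01. The lowest median of the windows over the 5 libraries was 1.95, so an extra chromosome I in nearly all cells may account for it. No biological reason for such a gain was tested.

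Tracts around active origins were narrower in pol2-S430A than in wild type at 90 min, by the largest half-width difference of the 7 comparisons (-14.1 kb). A later entry into S phase is argued against, since active origins were 8.09 points higher in pol2-S430A at 30 min. Depth is argued against, since the difference was -15.9 kb with libraries thinned to equal depth, and so is the choice of the G1 library or unreplicated level, since the highest upper bound over those settings was -3.90 kb. Copying from neighbouring origins is part of the measure, since the difference was -8.78 kb over origins with no neighbour within 40 kb. Slower or more often arrested forks in pol2-S430A may account for the narrower tracts. Less copying from neighbouring origins stays open for part of the difference. A difference between cultures stays open as well, because each strain had 1 library per time and no replicates.

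The difference made by pol2exo- in the excess at 10 kb relative to the centre had opposite signs with and without EXO1 at all 4 times in 10 mM HU: -4.68 to -2.55 points from rad53 and 6.96 to 12.0 points from rad53 exo1D. With EXO1 present the interval included 0 at each time and the half-width differences went both ways (-1.25 kb at 90 min, 1.57 kb at 120 min), so an opposite effect is not shown there, only a difference between the 2 effects. The 2 effects differed by 14.5 points at 90 min, a difference not tested across cultures, since there were no replicates; the interval over origins ran from 8.21 to 20.9, the smallest difference over the G1 and level settings was also 14.5, and the triple mutant at 90 min was 8.03 points above rad53 exo1D at 120 min (3.13 to 12.3). These values argue against the spread over origins, those settings and, at 90 min, a lead of up to 30 min in the triple mutant. The measure is a ratio to the centre. In rad53, rad53 pol2exo-, rad53 exo1D and the triple mutant the 90 min excess at 10 kb was 46.6%, 40.8%, 47.7% and 42.0%. The centres were 68.9%, 64.9%, 81.2% and 61.2%. At 120 min it was 42.0%, 33.7%, 39.8% and 31.9% at 10 kb and 61.0%, 52.2%, 65.8% and 46.5% at the centre. At both times the pattern thus rests on the height of the centre. At 60 min the excess at 10 kb was 43.2%, 40.9%, 33.7% and 47.2%. An effect of the POL2 exonuclease on profile shape that depends on EXO1 may account for the pattern. A lead of 30 min at the earlier times and single cultures stay open. So do other differences between the strains (13.6 points remained without chromosomes I and XII).

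Of 20 pairs of contrast and measure examined, 2 were opposite at every time, and the other was ppol2-S430D with and without EXO1 in 25 mM HU, where the effects on the excess at 10 kb relative to the centre differed by 12.1 points at 30 min (2.34 to 21.4 over origins), 5.16 at 60 min (-3.88 to 13.6) and 2.11 at 90 min (-7.11 to 11.7). The 90 min value turned to -0.957 with pooled G1 libraries, and these differences were not tested across cultures.

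Chromosome XII stood at 1.11 times the median chromosome in the G1 library of rad53 pol2exo- exo1D, against 0.973 to 1.02 in the other 9 strains.

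In G1, the mitochondrial genome stood at 17.8 times the nuclear level in ppol2-S430D, the highest value, and all 8 rad53 G1 libraries lay above both checkpoint-proficient ones, at 6.503 in wild type and 5.48 in pol2-S430A. The HU libraries did not keep this split, with 11.7 in pol2-S430A at 90 min, 8.04 in rad53 exo1D at 120 min and 8.26 in ppol2-S430D at 60 min.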

How the results depend on the processing

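The thinning to equal depth, the exclusion of chromosomes I and XII, isolation at 30 and 40 kb and the scale with the most copied windows at 2 copies were chosen after seeing the data, and the other settings before. Strains are named by what differs from their parent. Over the settings, half-width differences moved by less than their interval in 134 of 143 values and the excess at 10 kb relative to the centre in 137 of 143, and no such difference whose interval excluded 0 turned. For differences at active origins this held in 87 of 99 (1 turned), for genome means in 69 of 99 (9 turned) and for single origins in 399 of 420 (3 turned). The cause was not tested for any of the values that follow. Pooled G1 libraries do not fully divide out a chromosome raised in 1 strain, so chromosomes I and XII enter those 10 mM genome means. With the most copied windows at 2 copies, genome mean differences at 90 min turned to 1.85 (pol2exo-), -4.88 (exo1D), 5.38 (pol2exo- exo1D), 2.33 (S430D) and 7.82 (S430D exo1D) and moved to -0.484 (pPOL2 exo1D, also a change of sign) and -1.48 (S430A). Against the other single mutants they turned to 10.3 (pol2exo- exo1D against exo1D), 8.30 (S430D exo1D against pPOL2 exo1D) and 5.49 (against S430D). With pooled G1 libraries the genome mean differences were -1.62 (pol2exo-), 4.59 (exo1D), 0.272 (S430D, turned), 0.734 (pPOL2 exo1D) and -2.36 (S430D exo1D), active origins 14.7 (exo1D), -2.31 (S430D) and -8.04 (S430D exo1D), and 2 origins turned in pol2exo- exo1D, to -4.13 (XIII 553801) and 4.84 (XVI 331601). With the 20th percentile the genome mean differences were 2.16 (exo1D), -2.28 (pol2exo- exo1D), 0.660 (pPOL2 exo1D) and -3.14 (S430D exo1D). With no unreplicated level active origins were 6.45 (exo1D), -5.40 (S430D exo1D) and 5.17 (S430A, turned), the S430A half-width -5.81 kb (-10.3 and -8.78 kb with isolation at 30 and 40 kb), and inactive origins of wild type and pol2-S430A turned to -17.0% and -9.75%. Thinned, genome means were -1.75 (pol2exo-) and 3.53 (exo1D), and the origin at XV 438201 turned to 0.882 (pPOL2 exo1D). A GC correction was not run, a height of 0.25 of the centre was not reached within 30 kb at 90 min, and the genome mean has no value without a level. Depth limits single origins: 38% and 45% of simulated 20 point changes were called. With 1 library per strain, dose and time, leaving out a replicate was not applicable and no replicate numbers could be paired. Pairing by time, added after seeing the data, gives 3 or 4 pairs of times that are not replicates, and the exact permutation p cannot fall below 0.25 or 0.125; 10 of 28 such tests reached that limit.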

Other observations

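The comparisons of this part were chosen after their values were seen. A stretch at the left end of chromosome VII, from 801 to 6300 and holding COS12, a subtelomeric membrane protein gene, and YGL262W, was at full depth in the 10 libraries of the pol2exo- strains and nearly empty in the other 36. In G1 it held 1979 counts in rad53 pol2exo- and 1698 in rad53 pol2exo- exo1D, or 1.03 and 0.908 times the median bin, against at most 3 counts in the other 8 strains. A stretch from 324401 to 325800 on chromosome IX, holding the small gene YIL014C-A beside BAR1, the protease gene that degrades α-factor, was nearly empty in the 5 libraries of rad53 pol2exo- alone, with 1 to 6 counts, while BAR1 stood at 1.07 times the median gene. The pol2exo- strains therefore differed from the others at more places than their labels name, and comparisons that involve them carry these differences.

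The spacer of the ribosomal DNA array, read over the mean kept bin, differed between strains in G1. It stood at 207 in wild type, 166 in pol2-S430A, 158 in rad53, 197 in rad53 pol2exo-, 136 in rad53 pol2exo- exo1D, 102 in rad53 exo1D, 137 in pPOL2, 133 in ppol2-S430D, 141 in pPOL2 exo1D and 71.4 in ppol2-S430D exo1D. Over all libraries of a strain it ran from 163 to 225 in wild type, 128.5 to 174 in pol2-S430A and 186 to 209 in rad53 pol2exo-, so several strains overlapped, while it ran from 98.8 to 112 in rad53 exo1D and 69.6 to 74.6 in ppol2-S430D exo1D, below every library of the other strains. Cultures were not replicated and how reads of repeats were mapped is not given in the sources used here.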
